A study of Homo sapiens with 30 samples.

How the data were processed

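RNA of the lymphoblastoid lines GM15036 and GM15510 was measured on 30 Affymetrix arrays, 3 for each line at 1, 2.5, 5, 7.5 and 10 cGy, and each array is a sample of its own in the sources used here. Per the labels' protocols, cells were grown in suspension in MEM with serum and irradiated with a caesium source, and total RNA was extracted with Qiagen reagents and labelled with biotin by a 3-prime in vitro transcription method. Per the design text of the series, RNA was amplified with a T7 method of Arcturus and hybridised to triplicate arrays. The values are array signal intensities on a linear scale that the authors computed with MAS5, per the submitters' processing notes, with the version, scaling target and background settings not given in the sources used here. The values themselves are positive, not logged and not brought to a common level. The probe annotation of the platform can be old, so its symbols were updated through the gene ID with a RefSeq table of assembly GRCh38, which matched 19059 probe sets. Of 22283 probe sets, 19071 had 1 gene symbol, 1043 several and 2169 none, and only probe sets with 1 symbol were named.

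The test plan, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined, apart from the additions named below. The plan let values enter as deposited unless the trimmed means of the arrays, over the 2 to 98 percent range of values, differed by over 1.2 times. They differed by 7.91 times, so each array was scaled to the mean of the trimmed means, 50.9. A pseudocount of 4 was added before taking log2, the power of 2 nearest to the 25th percentile of all values, 3.41. A difference on this log2 scale understates the change of dim probe sets. After 68 control probe sets and 61 probe sets of XIST, TSIX and Y-linked genes were left out, the 40 percent of probe sets with the lowest mean log2 value (under 3.64) were left out too, which left 13309 for testing, 11636 of them with 1 symbol.

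Tests were run with limma 3.58.1 in R 4.3.3, with lmFit on the 10 groups of line and dose and eBayes with an intensity trend, two-sided. All 30 arrays entered each fit and share one estimate of the spread (20 residual and 12.3 prior degrees of freedom), since each group alone has 3 arrays. The comparisons were each dose against 1 cGy within a line, a linear slope of the 5 group means on dose in log2 per cGy, an F test of any difference among the doses of a line (4 numerator degrees of freedom), the same F test for the line by dose interaction, the difference of the slopes and the difference of the lines averaged over doses. Every adjusted p is limma's, or camera's for a list, with Benjamini-Hochberg adjustment, over the tested probe sets or over all tests of lists, and the threshold was 0.05. Comparisons within a line share the 1 cGy arrays, so no overlap between them is given. Overlap between the lines was tested with Fisher's exact test.

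The 23 gene lists covered p53 targets, DNA repair, G1/S, G2/M, apoptosis, NF-kB targets, interferon-stimulated, heat shock, ER stress, immediate-early, oxidative stress, cholesterol synthesis, glycolysis, nucleolar, ribosomal protein, oxidative phosphorylation, histone, B cell identity and plasma cell genes, and markers of T and NK cells, monocytes, erythroid cells and fibroblasts. Lists of at least 5 measured members were tested on 8091 genes with camera at a preset correlation of 0.01. Tests with an estimated correlation and with fry followed. Each gene had 1 probe set (highest mean, _x_at and _s_at sets only for lack of others). Genes were named by rule. For a pair of doses these were the 10 highest and 10 lowest changes past the threshold whose arrays did not overlap between the doses, a pattern that chance gives for 10% of probe sets with 3 arrays against 3. For the line difference, the sign had to be the same at all 5 doses, and for slopes the threshold alone counted. The F tests gave the 10 smallest p, each list up to 4 members past the threshold, and 20 radiation-response and stress genes were given whatever their test. Further members of lists, among them those that moved against their list, were named after their values were seen, as the text says. Not all genes under the rule are printed, and those printed were mostly ones that passed when each array was left out. Where other probe sets of genes named with their errors did not pass or went the other way, the text says so. HLA genes, immunoglobulin genes and genes with common whole-gene deletions were not named, because their level can show a donor's genotype, and after the values were seen ERAP2, MICA, MICB and UGT2B15 were left unnamed for the same reason.

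Alternative settings fixed in advance were quantile normalization, centring each unscaled array on its median log2 value, pseudocounts of 1 and 16, no filter and a filter of 60 percent, eBayes without a trend and robust eBayes, limma's array weights, each line fitted alone, the replicate label as a block, the log2 ratio of the 3-prime to the 5-prime GAPDH control as a covariate, 1 probe set per gene, a threshold of 0.01 and leaving out each array in turn. Chosen after seeing the data were log2 array brightness as a covariate, the fit without the 5 arrays with a trimmed mean under 20, centring each array on its median after scaling, leaving out each array in the tests of lists, and leaving each dose out of the slopes in turn. Ranges and highest values over the alternatives of a slope cover those that kept all 5 doses. Random lists matched on mean expression were drawn 10000 times.

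The fits were tested on simulated data with 13309 probe sets, 100 of them changed at each size. Of changes of 1 on the log2 scale, the fit recovered 51% for 10 cGy against 1 cGy in GM15036, 53% for 2.5 cGy against 1 cGy in GM15510, 94% for the line difference and 35% for the interaction. Of changes of 0.5 it recovered 23%, 14%, 68% and 8% in the same order. A simulated slope of 0.1 per cGy in GM15510 was recovered for 56% and a slope of 0.05 for 15%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.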

Results

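Messenger RNA was measured in GM15036 and GM15510, a pair of established human lymphoblastoid lines, which are B cells immortalised with Epstein-Barr virus and grown in suspension. The cells were exposed to radiation from a caesium source at 1, 2.5, 5, 7.5 or 10 cGy. Each line and dose had 3 arrays, which makes 10 groups and 30 arrays, and 13309 of the 22283 probe sets entered the tests. The sample labels give the doses in cGy, whereas the design text of the series gives the same numbers in Gy, and the unit of the labels is used here. No unirradiated group was analysed here, so each dose was compared with 1 cGy of the same line, and a change common to all 5 doses cannot be seen. The time between irradiation and RNA isolation is not given in the sources used here. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

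The arrays differed in brightness between doses. Mean brightness, the trimmed mean of the unscaled signal, was 69.7 ± 10.2 (SD, n = 3) at 1 cGy in GM15036 and 22.1 ± 10.4 at 10 cGy. In GM15510 it was 69.4 ± 10.5 at 1 cGy, 18.7 ± 4.48 at 2.5 cGy, 39.0 ± 26.6 at 5 cGy, 67.8 ± 21.8 at 7.5 cGy and 89.1 ± 23.6 at 10 cGy. Single arrays ranged from 14.1 to 112. GAPDH, a glycolytic enzyme whose control probe sets also report RNA integrity, had a log2 ratio of 3-prime to 5-prime signal of 2.52 ± 0.171 at 1 cGy and 2.84 ± 0.118 at 10 cGy in GM15036. In GM15510 the same ratio was 2.47 ± 0.108 at 1 cGy and 2.45 ± 0.184 at 10 cGy. ACTB, the cytoskeletal actin with control probe sets of the same kind, had a log2 ratio of 4.48 ± 0.204 at 1 cGy in GM15036 and means of 5.03 to 5.51 at the higher doses. In GM15510 the ACTB ratio went from 3.75 ± 0.489 at 1 cGy to 5.16 ± 0.096 at 10 cGy. Arrays of the same group correlated at 0.901 to 0.972 over the tested probe sets, arrays of different lines at 0.857 to 0.945, and 0 pairs held identical values. Other scalings moved the balance of higher and lower calls, and with it the median log2 change of all probe sets against 1 cGy. When the unscaled arrays were centred on their medians, that median was −0.12, −0.20 and −0.38 at 2.5, 7.5 and 10 cGy in GM15036, and −0.50 and −0.29 at 2.5 and 5 cGy in GM15510. When the scaled arrays were centred on their medians, it was −0.20 at 10 cGy in GM15036 and −0.28 and −0.16 at 2.5 and 5 cGy in GM15510. These settings are called median centring and centring after scaling, in that order, and every signed change is relative to the scaling of the main setting.

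**Figure D1:**
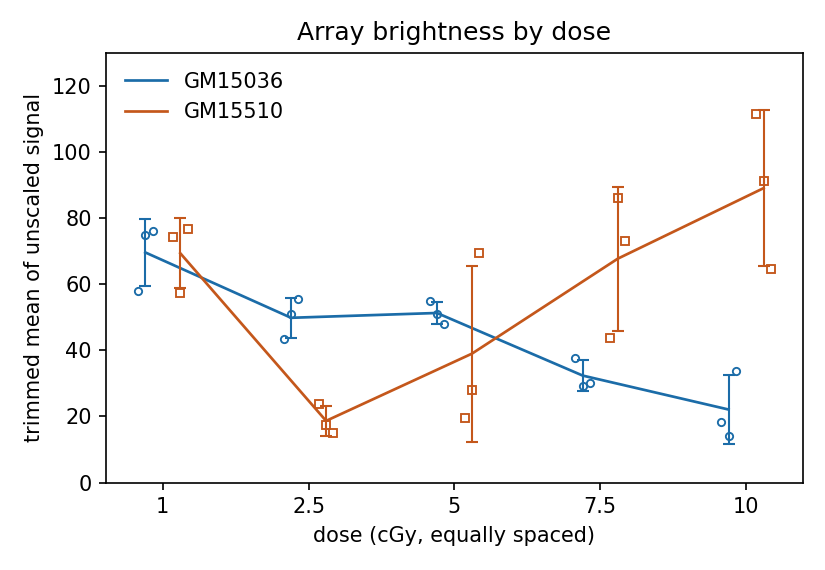
Trimmed mean of the unscaled signal of each array against dose in cGy (doses equally spaced), with circles for GM15036, squares for GM15510, lines through the means and error bars for the SD of 3 arrays. GM15036 goes from 69.7 at 1 cGy to 22.1 at 10 cGy, and GM15510 is at 18.7 at 2.5 cGy and 89.1 at 10 cGy.

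At 10 cGy, GM15036 cells held less mRNA of mitosis genes than at 1 cGy. CCNB1 and CCNB2, the cyclins that drive entry into mitosis, fell by 0.75 (SE 0.088) and 0.86 (SE 0.096) on the log2 scale, with 3 arrays per dose and adjusted p = 6.82e-07 and 3.49e-07. HMMR, a protein of the mitotic spindle, fell by 0.91 (SE 0.112, adjusted p = 1.32e-06). Of 39 measured G2/M and mitosis genes, 14 fell and 1 rose, or 17 and 1 when adjusted over the list alone, and the list passed the camera test (median log2 change −0.33, adjusted p = 8.1e-07). The member that rose was MKI67, a proliferation marker, at 0.38 (adjusted p = 0.0207), named after its value was seen, and 0 of its 3 other probe sets passed. MKI67 turned to −0.27 under median centring, had adjusted p = 0.504 with centring after scaling, the highest over its alternatives, and lost its call without 1 cGy replicates b (0.0603) and c (0.0839) and 10 cGy replicates b (0.0923) and c (0.077). Of 32 G1/S and replication genes, 8 fell and 0 rose, or 10 and 0 when adjusted over the list alone. Among them were RFC3, a subunit of the clamp loader of DNA replication, at −0.82 (adjusted p = 2.36e-07), and MCM6, part of the replicative helicase, at −0.66 (adjusted p = 9.8e-06). The G1/S list (median −0.20, adjusted p = 0.0091) had adjusted p = 0.0634 with an estimated correlation, the highest of 12 alternatives that began at 2.95e-05, and 0.0704 without GM15036 1 cGy replicate a. Glycolysis and hypoxia genes fell too, 8 of 29 with 0 higher, or 9 and 0 when adjusted over the list alone (median −0.20, adjusted p = 0.0058). ENO1, the glycolytic enzyme enolase, fell by 0.91 (SE 0.092, adjusted p = 6.4e-08), and its other probe set had −0.68 and did not pass. KDM3A, a histone demethylase, had −0.74, P4HA1, a collagen prolyl hydroxylase, had −0.55, and GPI, the glucose phosphate isomerase of glycolysis, had −0.52, each past the threshold. All genes named here as lower passed without each of the 30 arrays and under every alternative. Beside each of these lists, brightness was 22.1 at 10 cGy and 69.7 at 1 cGy, and the ACTB ratio 5.20 and 4.48.

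Ribosomal protein genes moved the other way in GM15036 at 10 cGy, except under median centring, where their direction turned to lower (adjusted p = 0.15). Of 52 cytosolic ribosomal protein genes, 16 rose and 1 fell, or 25 and 1 when adjusted over the list alone (median 0.25, adjusted p = 3.2e-07). The list had adjusted p = 0.10 with an estimated correlation and a range of 1.49e-08 to 0.15 over the 12 alternatives. RPS19 and RPL12, structural proteins of the small and the large subunit, had 0.63 and 0.62 with 3 arrays per dose, and the member that fell was RPL22 at −0.42, named after its value was seen, although another RPL22 probe set rose by 0.32. RPL22 had adjusted p = 0.281 with brightness as a covariate, the highest over its alternatives. In all, 1563 probe sets passed at 10 cGy, 583 higher and 980 lower. Median centring gave 74 higher and 4249 lower, and centring after scaling 123 and 2180. Among single genes, CYP27A1, the sterol 27-hydroxylase, was higher by 2.66 (SE 0.412, adjusted p = 3.59e-05), but by 1.87 with brightness as a covariate, where its adjusted p was 0.0778, the highest over the alternatives. Brightness as a covariate left 365 calls and the GAPDH ratio 955.

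At 7.5 cGy, GM15036 cells had more mRNA of ribosomal proteins than at 1 cGy, a direction that every scaling kept. Of 52 ribosomal protein genes, 25 rose and 0 fell, or 35 and 0 when adjusted over the list alone (median 0.36, adjusted p = 2.3e-29). RPS19 rose by 0.67 and RPS18 by 0.48, each without exception over the 30 arrays left out in turn, although median centring gave 0.36 and 0.17 with adjusted p = 0.232 and 0.584, the highest over their alternatives. FTL, the light chain of the iron store ferritin, rose by 0.86 (SE 0.1, n = 3, adjusted p = 1.03e-05), and its other probe set by 1.01. CYP27A1 was higher by 2.49 (SE 0.412, adjusted p = 4.23e-04). SQLE, the squalene epoxidase of cholesterol synthesis, fell by 0.77 (SE 0.134, adjusted p = 7.09e-04), while its other probe set had −0.21 and did not pass. FTL, CYP27A1 and SQLE passed under every alternative and without each array. Cholesterol synthesis genes were lower as a list, with SQLE and SC5D of 16 past the threshold, or 5 when adjusted over the list alone (median −0.15, adjusted p = 0.037), and had adjusted p = 0.095 with an estimated correlation, within a range of 0.00219 to 0.164. That call ended without GM15036 1 cGy replicate a (0.206), 7.5 cGy replicate b (0.165) and 7.5 cGy replicate c (0.0533). SC5D, a sterol desaturase, had −0.61, and lost its call without 1 cGy replicate c (0.0622).

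Mitosis genes were also lower as a list at 7.5 cGy in GM15036 (median −0.12, adjusted p = 0.032), with 2 of 39 past the threshold, TTK at −0.55 and HMMR at −0.45, or 3 when adjusted over the list alone. TTK lost its call without 1 cGy replicate b (0.08), and HMMR without 1 cGy replicate c (0.0948), 7.5 cGy replicate a (0.0879) and 7.5 cGy replicate b (0.0808). The list lost its call without 1 cGy replicate a (0.0529), 1 cGy replicate b (0.0512) and 7.5 cGy replicate a (0.159), and with brightness as a covariate (0.279, in a range from 6.3e-05). Oxidative phosphorylation subunits were higher (median 0.18, adjusted p = 9.1e-04), 4 rising and 1 falling of 58, or 8 and 1 when adjusted over the list alone, but had adjusted p = 0.373 under median centring, in a range from 1.83e-04. ATP5ME, a subunit of ATP synthase, had 0.69 (adjusted p = 0.00107) and passed without each array. COX6B1, a cytochrome c oxidase subunit, had 0.60 and lost its call without 1 cGy replicate b (0.0684). NDUFC1 and NDUFV2, of complex I, had 0.62 and 0.44, where NDUFV2 was named after its value was seen and lost its call without 19 of the 30 arrays, and ATP5F1B, the catalytic subunit of ATP synthase, had −0.34. NDUFC1 and ATP5F1B lost their calls without 1 cGy replicates a (0.0905 and 0.0748) and b (0.222 and 0.131) and 7.5 cGy replicate b (0.0857 and 0.103), NDUFC1 also without 7.5 cGy replicate c (0.211) and ATP5F1B without a (0.0591). In all, 429 probe sets passed at 7.5 cGy, 169 higher and 260 lower, with 18 and 557 under median centring and 45 and 227 under centring after scaling, and 134 in all with brightness as a covariate. That count was 185 without 1 cGy replicate b, 245 without 1 cGy replicate c, 198 without 7.5 cGy replicate b and 233 without 7.5 cGy replicate c. Brightness was 32.4 ± 4.73 at this dose, the GAPDH ratio 2.82 ± 0.278 and the ACTB ratio 5.40 ± 0.154.

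The lower doses had fewer calls in GM15036, 73 at 2.5 cGy and 19 at 5 cGy. These counts were 382 and 166 with array weights and 126 and 50 without the 5 dimmest arrays, and 1260 and 1063 probe sets had an unadjusted p under 0.05. At 2.5 cGy, TAF1D, a factor of RNA polymerase I, fell by 0.70 (SE 0.119, n = 3, adjusted p = 0.00267), GNG5, a G protein gamma subunit, by 0.69 (SE 0.116, adjusted p = 0.00263), GALNT7, an enzyme of O-glycosylation, by 0.68 (SE 0.101, adjusted p = 0.00167). So did TMED5, a cargo protein between ER and Golgi, by 0.61 (SE 0.101, adjusted p = 0.00263). These 4 were the named genes that passed without each array, and they passed under every alternative, while another TMED5 probe set, at −0.17, did not pass. Of the 73 probe sets at 2.5 cGy, 16 were higher and 57 lower, with 3 and 27 under median centring and 1 and 80 under centring after scaling. The count was 30, 16 and 36 without 1 cGy replicates a, b and c, and 27, 22 and 25 without 2.5 cGy replicates a, b and c. Of the 19 at 5 cGy, 7 were higher and 12 lower, and EMC7, a subunit of the ER membrane complex, had 0.48 (SE 0.081, adjusted p = 0.00319). EMC7 had adjusted p = 0.0603 without 1 cGy replicate b and 0.0763 without 5 cGy replicate a, and 0 of the 9 named genes that passed limma's test at 5 cGy did so without each array. The count at 5 cGy was 2 and 12 without 1 cGy replicates b and c, 4, 5 and 6 without 5 cGy replicates a, b and c, 33 without GM15510 2.5 cGy replicate 3 and 32 without GM15510 5 cGy replicate 1. Median centring left 1 higher and 1 lower, centring after scaling 0 and 2.

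Gene lists at 2.5 and 5 cGy in GM15036 shifted with few single members past the threshold. Ribosomal protein genes were lower at both doses under every scaling, with median changes of −0.072 and −0.10 and adjusted p = 0.0037 and 4.5e-04. They had adjusted p = 0.382 and 0.287 with an estimated correlation, the highest of ranges that began at 5e-05 and 3.54e-06, and 0.219 and 0.123 without 1 cGy replicate a. At 2.5 cGy the members past the threshold were RPL23A at −0.48 and RPL35A at −0.47, also 2 when adjusted over the list alone, and at 5 cGy RPS24 at −0.44, also 1 when adjusted over the list alone. RPL23A and RPL35A lost their calls without 1 cGy replicates a (0.123 and 0.131) and b (0.071 and 0.0834) and 2.5 cGy replicates a (0.0845 each) and b (0.115 and 0.074), and RPL35A without 2.5 cGy replicate c (0.0718). RPS24 had adjusted p = 0.149 without 1 cGy replicate b, 0.0763 without 5 cGy replicate a and 0.115 without 5 cGy replicate b. Oxidative phosphorylation subunits were lower at 2.5 cGy (median −0.099, adjusted p = 0.012), with 0 of 58 past limma's threshold, 2 lower when adjusted over the list alone and 7 lower at an unadjusted p under 0.05. They had adjusted p = 0.058 with an estimated correlation, in a range of 0.00141 to 0.0631, with 0.089 without 1 cGy replicate a and 0.0504 without 2.5 cGy replicate b. ER stress and amino acid response genes were higher at 5 cGy (median 0.19, adjusted p = 0.0034), with 0 of 35 past limma's threshold, also 0 when adjusted over the list alone, and 7 higher and 3 lower at an unadjusted p under 0.05. That list had adjusted p = 0.0552 under median centring, in a range from 0.00213, and 0.0721 without 5 cGy replicate a. Brightness at 2.5 and 5 cGy was 49.9 ± 6.13 and 51.3 ± 3.48, and the ACTB ratio 5.51 ± 0.363 and 5.03 ± 0.0724.

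Across all 5 doses in GM15036, mitosis genes fell and ribosomal protein genes rose as lists. CCNB1 fell by 0.075 (SE 0.0085) log2 per cGy, but its means against 1 cGy were 0.066, 0.28, −0.086 and −0.75 at 2.5, 5, 7.5 and 10 cGy, and without 10 cGy its slope was −0.0051 (adjusted p = 0.918). HMMR, TTK, a kinase of the spindle checkpoint, and CCNB2 had −0.094, −0.092 and −0.075 per cGy. Without 10 cGy TTK had −0.083 (adjusted p = 0.00731), while HMMR and CCNB2 had −0.047 and −0.0056 and did not pass (0.119 and 0.916). Of 39 mitosis genes, 18 fell with dose and 1, MKI67 at 0.041 per cGy, rose, or 19 and 1 when adjusted over the list alone (median −0.028, adjusted p = 9.1e-07), and without 10 cGy the list had a median of −0.019 and adjusted p = 0.0877. MKI67 had adjusted p = 0.674 without 10 cGy, and turned to −0.021 under median centring. Of 52 ribosomal protein genes, 33 rose and 2 fell with dose, or 36 and 2 when adjusted over the list alone (median 0.040, adjusted p = 1.8e-21), but the list had adjusted p = 0.418 under median centring, in a range from 7.71e-22, and 9.94e-32 without 10 cGy. RPL22 and RPL37A were the members that fell, at −0.030 and −0.054, of which RPL22 lost its call without 10 cGy replicate b (0.0673) and turned to 0.013 without 10 cGy, and RPL37A lost its call without 8 of the 30 arrays and without 2.5 (0.123), 7.5 (0.135) or 10 cGy (0.256). Glycolysis genes fell with dose (9 of 29, also 9 when adjusted over the list alone, median −0.023, adjusted p = 0.003), led by ENO1 at −0.086. At 5 cGy the list median per array had a mean of 0.096 ± 0.013 (SD, n = 3) and ENO1 had 0.13, which did not pass. Without 10 cGy the list had adjusted p = 0.74 and ENO1 −0.015 (0.693). G1/S genes fell as well (9 lower and 1 higher of 32, or 10 and 1 when adjusted over the list alone, median −0.023, adjusted p = 0.0054), with GINS2, part of the replication fork complex, as the exception at 0.032. GINS2 lost its call without 21 of the 30 arrays and without each dose other than 1 cGy (0.0553 to 0.284), and turned to −0.028 under median centring and −0.0068 with brightness as a covariate. MKI67, RPL22, RPL37A and GINS2 were named here after their values were seen. The G1/S slope had adjusted p = 0.0522 with an estimated correlation, in a range from 5.83e-06 with all doses kept, and 0.395 without 10 cGy. ICAM4, a cell adhesion glycoprotein, rose by 0.15 per cGy (SE 0.032, adjusted p = 0.00184), and HBP1, a transcriptional repressor, fell by 0.15 (SE 0.031, adjusted p = 0.00139), each under every alternative that kept all doses, but without 10 cGy they had adjusted p = 0.296 and 0.385. In all, 1731 probe sets had a slope that passed, 695 up and 1036 down, with 79 and 4179 under median centring and 213 and 2008 under centring after scaling, 396 in all with brightness as a covariate and 358 without 10 cGy. The F test over all doses called 2152 probe sets, with ENO1 (F = 39.6, adjusted p = 1.34e-08) among the highest.

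At 2.5 cGy in GM15510, the dose with its dimmest arrays, LRRC1, a scaffold protein of cell polarity, fell by 2.08 (SE 0.316, n = 3, adjusted p = 4.77e-05), which is 4.22-fold, while its other probe set had −0.12 and did not pass. RPS27, a small-subunit ribosomal protein, fell by 0.73 (adjusted p = 2.14e-07), and both genes passed without each array and under every alternative. Ribosomal protein genes were higher as a list (median 0.16, adjusted p = 1.9e-04), with 14 rising and 5 falling of 52, or 17 and 6 when adjusted over the list alone, but turned to lower under median centring (adjusted p = 0.0217). They had adjusted p = 0.27 with an estimated correlation, in a range of 1.3e-04 to 0.328. RPL3 of the large subunit had 1.00 and RPS3 of the small subunit 0.73, against −0.40 for RPS24, −0.44 for RPS15A, −0.47 for RPS29 and −0.38 for RPL23A, which were named after their values were seen. With brightness as a covariate RPS15A, RPS29 and RPL23A had adjusted p = 0.0946, 0.665 and 0.449, the highest over their alternatives. RPS29 lost its call without 1 cGy replicate 1 (0.108) and 2.5 cGy replicate 3 (0.0768), and RPL23A without 1 cGy replicates 2 (0.0601) and 3 (0.0532). In all, 1261 probe sets passed, 521 higher and 740 lower, with 74 and 5614 under median centring and 125 and 2554 under centring after scaling. That count was 732, 838 and 806 without 1 cGy replicates 1, 2 and 3, and 114 with brightness as a covariate. Brightness was 18.7 at 2.5 cGy against 69.4 at 1 cGy, and the GAPDH ratio 2.27 ± 0.106 against 2.47 ± 0.108 and the ACTB ratio 4.29 ± 0.558 against 3.75 ± 0.489.

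At 5 cGy in GM15510, SPDL1, a spindle checkpoint protein, fell by 1.00 (SE 0.184, n = 3, adjusted p = 8.8e-04). ZC3H7B, a zinc finger protein, rose by 1.12 (SE 0.131, adjusted p = 1.54e-06). Both passed without each array and under every alternative, but other probe sets of ZC3H7B (0.36 and 0.23) did not pass. Ribosomal protein genes split, 11 rising and 5 falling of 52, or 21 and 7 when adjusted over the list alone, with a higher list (median 0.11, adjusted p = 9.1e-04) that turned to lower under median centring (adjusted p = 0.396). The list had adjusted p = 0.31 with an estimated correlation, in a range of 6.05e-04 to 0.524. The members that fell were RPS27 at −0.46, RPL23A at −0.51, RPL22 at −0.41, RPS24 at −0.33 and RPL29 at −0.48, of which RPS27 and RPL23A passed under every alternative and the other 3 were named after their values were seen. RPS24 lost its call without 1 cGy replicate 2 (0.0535), RPL29 without 24 of the 30 arrays, and RPL22 had adjusted p = 0.0881 with brightness as a covariate, the highest over its alternatives. p53 target genes were higher as a list (median 0.20, adjusted p = 0.032), with 0 of 21 past limma's threshold, or 3 higher and 1 lower when adjusted over the list alone and 6 and 1 at an unadjusted p under 0.05. Their list had adjusted p = 0.12 with an estimated correlation, in a range of 0.0085 to 0.268, and 0.0502 without 1 cGy replicate 1, 0.0592 without 5 cGy replicate 1 and 0.153 without 5 cGy replicate 3. In all, 558 probe sets passed, 276 higher and 282 lower, with 44 and 1917 under median centring and 103 and 694 under centring after scaling. The count was 306 without 1 cGy replicate 1, 285 without 1 cGy replicate 3, 322 without 5 cGy replicate 1 and 364 without 5 cGy replicate 2b. Brightness at 5 cGy was 39.0 ± 26.6, and the ACTB ratio was 4.81 ± 1.2.

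At 7.5 cGy in GM15510, SEC11A, the catalytic subunit of the signal peptidase of the ER, rose by 0.71 (SE 0.0999, n = 3, adjusted p = 1.96e-04), and ZNF22, a zinc finger protein, fell by 0.81 (SE 0.117, adjusted p = 2.11e-04). Both passed without each array, but SEC11A had adjusted p = 0.16 under median centring, the highest over its alternatives, and another probe set of each, at 0.074 and −0.11, did not pass. FDPS, the farnesyl diphosphate synthase of the mevalonate route, rose by 0.51 (SE 0.095, adjusted p = 0.00285), with 0.44 and adjusted p = 0.418 under median centring, the highest over its alternatives. FDPS was the member past the threshold, also when adjusted over the list alone, of 16 cholesterol synthesis genes, which were higher as a list (median 0.16, adjusted p = 0.0058). Plasma cell differentiation genes were higher too (median 0.22, adjusted p = 0.011), with MZB1 at 0.44 as the member of 14 past the threshold, or 4 higher and 1 lower when adjusted over the list alone. The plasma cell list had adjusted p = 0.054 without 7.5 cGy replicate 1, and MZB1, a plasma cell chaperone of the ER, had 0.18 without it and 0.113 without 1 cGy replicate 1. In all, 237 probe sets passed, 138 higher and 99 lower, with 3 and 4 under median centring and 36 and 47 under centring after scaling. That count was 77, 147 and 104 without 1 cGy replicates 1, 2 and 3, and 79 and 110 without 7.5 cGy replicates 1 and 3. Brightness was 67.8 at 7.5 cGy and 69.4 at 1 cGy.

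At 10 cGy in GM15510, BAX, a pro-apoptotic pore protein of mitochondria, rose by 1.24 (SE 0.167, n = 3, adjusted p = 6.42e-06), and its other probe set by 1.38. HIPK2, a kinase that phosphorylates p53, rose by 2.43 (SE 0.283, adjusted p = 5.35e-07), which is 5.39-fold, but its other probe set had 0.17 and did not pass. MCL1, an anti-apoptotic protein, rose by 1.24 (SE 0.142, adjusted p = 4.21e-07), while its other probe sets had 0.55, 0.082 and 0.19 and did not pass. VAMP8, a SNARE protein of vesicle fusion, rose by 1.26 (SE 0.111, adjusted p = 1.69e-09). NUP43, a nuclear pore protein, fell by 1.39 (SE 0.108, adjusted p = 1.23e-10), CASP8, the initiator caspase of death receptors, by 1.25 (SE 0.221, adjusted p = 3.3e-04). TARS1, the threonyl-tRNA synthetase, fell by 0.96 (SE 0.082, adjusted p = 1.2e-09). These 7 genes passed without each array and under every alternative. Of 22 genes of the apoptosis machinery, MCL1 rose and CASP8 fell, also 1 and 1 when adjusted over the list alone, and the list did not pass (median 0.14, adjusted p = 0.39). Of 21 p53 target genes, BAX and DDB2 rose and 0 fell, or 3 and 0 when adjusted over the list alone (median 0.24, adjusted p = 0.027). The list had adjusted p = 0.10 with an estimated correlation, in a range of 0.00199 to 0.102, and 0.0768 without 10 cGy replicate 1. In all, 787 probe sets passed, 411 higher and 376 lower, with 148 and 48 under median centring and 252 and 217 under centring after scaling. The count was 514 and 509 without 1 cGy replicates 1 and 2, and 478 without 10 cGy replicate 3. Brightness was 89.1 at 10 cGy, the highest group mean, and 69.4 at 1 cGy, and the ACTB ratio was 5.16 ± 0.096 and 3.75 ± 0.489.

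**Figure D2:**
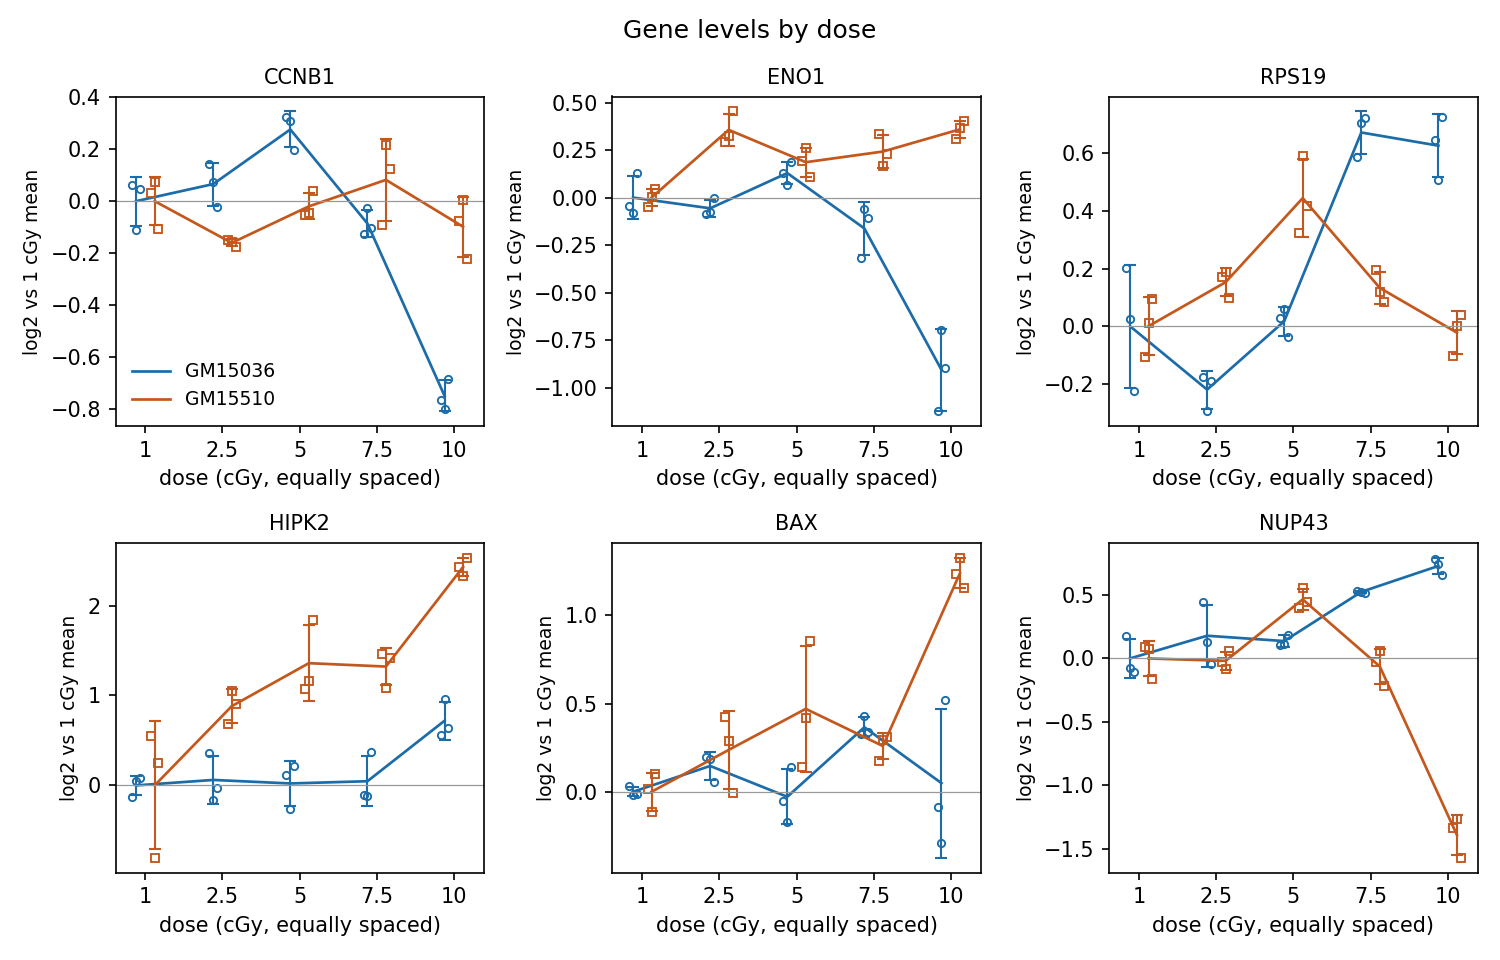
Log2 change of 6 genes against the 1 cGy mean of their line at each dose in cGy (doses equally spaced), per array, with circles for GM15036, squares for GM15510, lines through the means and error bars for the SD of 3 arrays. At 10 cGy CCNB1 is at −0.75 in GM15036 and −0.098 in GM15510, NUP43 at 0.73 and −1.39, and RPS19 at 0.63 in GM15036, a direction that median centring turns to −0.033.

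Over all doses in GM15510, HIPK2 rose by 0.23 log2 per cGy (SE 0.027, adjusted p = 2.5e-06), MCL1 by 0.12 (SE 0.014, adjusted p = 2.19e-06) and BAX by 0.11 (SE 0.016, adjusted p = 4.59e-05). NUP43 fell by 0.13 per cGy (SE 0.0105, adjusted p = 6.25e-10) and CASP8 by 0.11 (SE 0.0215, adjusted p = 0.00178). The means of NUP43 against 1 cGy were −0.019 at 2.5 cGy, 0.47 ± 0.081 (SD, n = 3) at 5 cGy, −0.063 at 7.5 cGy and −1.39 at 10 cGy. Its rise at 5 cGy, singled out after its value was seen, passed (adjusted p = 0.0085), but not under median centring (0.863, the highest over its alternatives) or without 1 cGy replicate 3 (0.0863) or 5 cGy replicate 2b (0.0533). Without 10 cGy HIPK2 and FDPS, of the 27 named slopes, passed in the same direction, at 0.19 (adjusted p = 0.00943) and 0.056 (0.0204). MCL1 and BAX had 0.0079 and 0.042 (0.927 and 0.471), and NUP43 and CASP8 turned to 0.011 and 0.031 (0.838 and 0.756). The other HIPK2 probe set had 0.040 and did not pass. With brightness as a covariate the BAX slope was 0.064, with adjusted p = 0.0301, the highest over its alternatives that kept all doses. Cholesterol synthesis genes rose with dose (median 0.025, adjusted p = 0.0093), with FDPS at 0.074 as the member of 16 past the threshold, or 4 when adjusted over the list alone, and had adjusted p = 0.124 with brightness as a covariate, in a range from 2.81e-04, 0.313 without 1 cGy and 0.0696 without 7.5 cGy. Ribosomal protein genes fell with dose, 12 lower and 2 higher of 52, or 22 and 6 when adjusted over the list alone (median −0.019, adjusted p = 1e-06), but turned to higher under median centring (adjusted p = 0.341). They had adjusted p = 0.12 with an estimated correlation, in a range from 1.24e-07, and 0.206 without 10 cGy. The members that rose were RPL14 at 0.079 and RPL27A at 0.042, named after their values were seen, and both turned without 10 cGy, to −0.022 and −0.023. RPL14 lost its call without 1 cGy replicate 3 (0.0577), 10 cGy replicate 1 (0.058) or the 2.5 cGy dose (0.0616), and RPL27A without 7 of the 30 arrays or the 1 cGy dose (0.244). In all, 616 probe sets had a slope that passed, 363 up and 253 down, with 1668 and 33 under median centring and 521 and 62 under centring after scaling. That count was 406 without 1 cGy replicate 2 and 404 without 10 cGy replicate 1, and 1545 without 1 cGy and 305 without 10 cGy. The F test over all doses called 2789 probe sets, led by NUP43 (F = 83.9, adjusted p = 1.54e-12) and TARS1 (F = 55.8).

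Of 21 p53 target genes, MDM2 and TRIAP1 rose and PPM1D and FAS fell at 10 cGy in GM15036, or 3 and 3 when adjusted over the list alone, and the list did not pass (median 0.070, adjusted p = 0.97). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had 0.41 (SE 0.142, n = 3, adjusted p = 0.0586) at 10 cGy in GM15036 and 0.24 (adjusted p = 0.437) in GM15510. Its slope in GM15036 was 0.049 per cGy (SE 0.0137, adjusted p = 0.0133), but it turned to −0.0096 under median centring (adjusted p = 0.741) and had adjusted p = 0.629 with brightness as a covariate, in a range from 0.00389, and 0.0738 without 1 cGy replicate c, 0.0521 without 1 cGy and 0.188 without 10 cGy. MDM2, the ubiquitin ligase of p53, rose by 0.76 (SE 0.217, adjusted p = 0.0181) at 10 cGy in GM15036, and its other probe set had 0.65 and did not pass. MDM2 had adjusted p = 0.0594 and 0.0805 without 1 cGy replicates b and c, and 0.116 without 10 cGy replicate a. PPM1D, a phosphatase that dampens p53 signalling, fell by 0.97 (SE 0.173, adjusted p = 2.03e-04) and FAS, a death receptor, by 0.77 (SE 0.158, adjusted p = 9.28e-04) at 10 cGy in GM15036. With brightness as a covariate PPM1D and FAS had adjusted p = 0.149 and 0.147, the highest over their alternatives, and of the other FAS probe sets 1 was lower at −0.60 and passed, while −0.26 and −0.23 did not. DDB2, which recognises ultraviolet damage in DNA, rose by 0.76 (SE 0.167, adjusted p = 0.00362) at 10 cGy in GM15510, without each array and under every alternative. At 2.5 cGy DDB2 had 0.64 (SE 0.167, adjusted p = 0.0117) in GM15510, but −0.015 under median centring (adjusted p = 0.967, the highest over its alternatives).

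TNFRSF10B, a death receptor, had 0.36 (SE 0.088, n = 3, adjusted p = 0.027) at 7.5 cGy in GM15510, with 0.63 and −1.11 for its other probe sets, which did not pass, and lost its call without 1 cGy replicates 1 (0.0761) and 3 (0.183) and without 7.5 cGy replicates 1 (0.095) and 2 (0.101). EGR1, an immediate-early transcription factor, had −0.64 (adjusted p = 0.0431) at 2.5 cGy in GM15510, and 0.605 with brightness as a covariate, the highest over its alternatives. It lost its call without 1 cGy replicates 1 (0.153) and 2 (0.135) and without 2.5 cGy replicates 1 (0.136) and 2 (0.0862). GADD45A, XPC, SESN1, CCNG1, MYC, JUN and ATM passed in 0 of the 8 pairwise comparisons by limma. At an unadjusted p under 0.05, GADD45A, CCNG1 and ATM stood out in 2 each, SESN1 and MYC in 1 and XPC and JUN in 0. PCNA, the sliding clamp of DNA replication, passed in 0 of them as well, with 2 lower at an unadjusted p under 0.05, and its slope in GM15036, −0.038 per cGy (adjusted p = 0.0365), lost its call without 1 cGy replicates a (0.0594) and b (0.135), 2.5 cGy replicate c (0.0786), 7.5 cGy replicate c (0.0763) and 10 cGy replicates a (0.115) and b (0.0993), and without 2.5 cGy (0.121) or 10 cGy (0.547). CCNG1, a p53-induced cyclin, differed among the doses of GM15036 by the F test (F = 7.46, adjusted p = 0.00344) under every alternative. ATM, a kinase that signals DNA breaks, did so too (F = 5.87, adjusted p = 0.0118), but not without 2.5 cGy replicate c (0.0533) or 5 cGy replicate b (0.0738). FDXR, BBC3, HSPA1A and HSPA8 had no probe set of their own symbol alone, and FOS was below the filter.

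The lines differed in their course over dose. NUP43 rose by 0.079 log2 per cGy (SE 0.0105, adjusted p = 3e-06) in GM15036 and fell by 0.13 (SE 0.0105) in GM15510, a slope difference of −0.21 (adjusted p = 3.52e-11, 15 arrays per line), although in GM15510 its mean against 1 cGy was 0.47 at 5 cGy. ENO1 had a slope difference of 0.11 (adjusted p = 6.6e-07), ATP5F1B of 0.12 (adjusted p = 6.04e-08) and MCL1 of 0.11 (adjusted p = 2.52e-04), where positive means higher in GM15510. RFC3, MCM6 and GPI had 0.090, 0.087 and 0.087, and these 7 genes passed without each array and under every alternative that kept all doses. Without 10 cGy ATP5F1B and MCM6 passed at 0.077 and 0.089 (adjusted p = 0.0118 and 0.00537), NUP43, ENO1, RFC3 and GPI did not (0.157, 0.379, 0.144 and 0.592), and MCL1 turned to −0.0066 (0.957). G2/M genes had higher slopes in GM15510 (15 higher and 1 lower of 39, or 19 and 3 when adjusted over the list alone, median 0.054, adjusted p = 4.6e-06), with CCNB1 at 0.078 and KIF11, a spindle motor, at 0.10. CCNB1 and KIF11 had adjusted p = 0.188 and 0.27 with brightness as a covariate, the highest over their alternatives that kept all doses, and 0.553 and 0.882 without 10 cGy. The list had adjusted p = 0.141 without 10 cGy. The member that was lower was CENPF, a kinetochore protein, at −0.043. CENPF turned to 0.057 under median centring and 0.018 without 10 cGy, and lost its call without GM15036 1 cGy replicate c (0.0613), 10 cGy replicate b (0.0684) and without the 1 cGy (0.0524) or 2.5 cGy dose (0.053). Ribosomal protein genes had lower slopes in GM15510, 32 of 52 with 0 higher, or 33 and 3 when adjusted over the list alone (median −0.054, adjusted p = 5.6e-23), but adjusted p = 0.996 under median centring, in a range from 2.82e-23. Glycolysis genes had higher slopes in GM15510 (6 of 29, or 7 when adjusted over the list alone, adjusted p = 0.012), with adjusted p = 0.0522 with an estimated correlation, in a range from 1.59e-05 with all doses kept, and 0.628 without 10 cGy. G1/S genes did as well (11 higher and 2 lower of 32, or 12 and 2 when adjusted over the list alone, adjusted p = 0.012), with GINS1 and CCNE1 as the lower members at −0.094 and −0.073. That list had adjusted p = 0.0811 with an estimated correlation, in a range from 5.8e-05 with all doses kept, 0.0521 without GM15036 1 cGy replicate a and 0.604 without 10 cGy. GINS1 turned to 0.0074 under median centring and had adjusted p = 0.0575 without 10 cGy. CCNE1 turned to 0.017 under median centring and lost its call without 9 of the 30 arrays and without 1 cGy (0.499) or 10 cGy (0.448). CENPF and CCNE1 were named after their values were seen.

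Cholesterol synthesis genes had higher slopes in GM15510 than in GM15036, with FDPS, SQLE, ACAT2, MSMO1 and IDI1 past the threshold of 16, or 6 when adjusted over the list alone (median 0.033, adjusted p = 0.011). FDPS, at 0.079, passed under every alternative that kept all doses, but had adjusted p = 0.0756 without 1 cGy and 0.0631 without 10 cGy. SQLE, at 0.087, had adjusted p = 0.564 with brightness as a covariate, the highest over its alternatives, and 0.0849 without 7.5 cGy, and its other probe set had 0.0034. With brightness as a covariate ACAT2 and MSMO1 had adjusted p = 0.321 and 0.911, the highest over their alternatives, and MSMO1 had 0.22 without 1 cGy and 0.232 without 10 cGy. IDI1, named after its value was seen, lost its call without 20 of the 30 arrays and without each dose other than 1 cGy (0.0534 to 0.501). The list had adjusted p = 0.051 with an estimated correlation and 0.221 without the dim arrays, in a range from 6.83e-05 with all doses kept, and 0.311 without 1 cGy and 0.0844 without 7.5 cGy. Oxidative phosphorylation subunits had lower slopes in GM15510 (10 lower and 6 higher of 58, or 11 and 6 when adjusted over the list alone, median −0.025, adjusted p = 0.037), but turned to higher under median centring (adjusted p = 0.353), in a range from 0.00307 with all doses kept, and had adjusted p = 0.10 with an estimated correlation, 0.413 without 2.5 cGy and 0.522 without 7.5 cGy. That call ended without GM15036 1 cGy replicate c (0.0648), 7.5 cGy replicate c (0.0621) and 10 cGy replicate c (0.108), and without GM15510 2.5 cGy replicate 1 (0.0673) and 10 cGy replicate 2 (0.0546). By the test of all doses, 2733 probe sets had a dose response that differed between the lines, led by NUP43 (F = 78.6, adjusted p = 4.7e-12), VAMP8 and DLD (F = 37.3 each), and 1436 differed in slope, 875 higher and 561 lower in GM15510. These were 5125 and 88 under median centring, 2031 and 165 under centring after scaling, 136 and 83 with brightness as a covariate and 220 and 197 without 10 cGy. Brightness went from 69.7 to 22.1 between 1 and 10 cGy in GM15036 and from 69.4 to 89.1 in GM15510, and the ACTB ratio from 4.48 to 5.20 and from 3.75 to 5.16, beside each of these lists.

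Both lines shared more dose-dependent probe sets than independent lists would. Of 2152 called in GM15036 and 2789 in GM15510, 1085 were called in both, against 451 for independent lists, with an odds ratio of 5.64 (95% interval 5.1 to 6.24, Fisher's exact test, two-sided, p = 8.1e-251, over probe sets that are not independent of each other). The odds ratio was 3.41 with the lowest 60 percent left out, 9.23 with no filter and 9.58 under median centring. Across probe sets, the slopes of the lines correlated at r = −0.067 and rho = −0.064, and of 194 probe sets with a called slope in both lines, 63 had the same sign and 131 the opposite. That r was −0.40 with brightness as a covariate and −0.30 under median centring. At 10 cGy, 130 of 218 calls in both lines had the same sign.

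Between the lines, over all doses, ROBO1, a guidance receptor, was lower in GM15510 by −3.50 (SE 0.114, adjusted p = 2.06e-22), which is 11.3-fold. AQP3, an aquaglyceroporin, was lower by −2.64 (SE 0.073, adjusted p = 1.66e-24) and CXCL10, a chemokine induced by interferon, by −2.20 (SE 0.17, adjusted p = 1.02e-12). SERPINB1, an inhibitor of neutrophil proteases, was higher in GM15510 by 2.50 (SE 0.155), and both of its probe sets passed. MEST, an imprinted gene, was higher by 2.37 (SE 0.092, adjusted p = 1.58e-20). All 40 genes named for this comparison passed without each of the 30 arrays and under every alternative, with 15 arrays per line. In all, 6287 probe sets (47.2%) differed, 2731 higher and 3556 lower in GM15510, with 3646 and 1959 under median centring and 3653 and 2251 under centring after scaling.

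Interferon-stimulated genes were higher in GM15510 under every scaling, 23 of 34 with 2 lower, or 24 and 2 when adjusted over the list alone (median 0.31, adjusted p = 1.7e-06). IFIT1 and HERC5, antiviral effectors, had 1.07 and 1.00, and the lower members were BST2, which tethers virions to the cell surface, at −0.61 and IRF9, a transcription factor of the interferon response, at −0.32. The GAPDH ratio had group means of 2.47 to 2.84 in GM15036 and 2.27 to 2.47 in GM15510, and the ACTB ratio of 4.48 to 5.51 and 3.75 to 5.16, beside each list given here. With the GAPDH ratio as a covariate 4399 probe sets differed between the lines, against 6287 without it, and each of the 5 lists passed in the same direction, with adjusted p from 9.94e-06 to 0.0246. G2/M genes were higher in GM15510 (22 higher and 3 lower of 39, or 24 and 4 when adjusted over the list alone, median 0.20, adjusted p = 3e-05), with HMMR at 1.09 and CCNB1 at 0.89. The lower members were CKS2 at −0.28, PTTG1 at −0.16 and MKI67 at −0.75, and of the other MKI67 probe sets −0.56 and −0.47 were lower and 0.36 was higher. Heat shock genes were higher (9 of 18 with 1 lower, also 9 and 1 when adjusted over the list alone, median 0.15, adjusted p = 0.011), led by HSPH1, a chaperone of the HSP110 family, at 0.97, with HSF1, the heat shock transcription factor, lower at −0.57. Histone genes were higher (6 of 15, also 6 when adjusted over the list alone, median 0.38, adjusted p = 0.031), with H2AC6 at 1.24 and H2BC12 at 1.04, and had adjusted p = 0.063 with an estimated correlation, in a range of 8.66e-11 to 0.0784. Cholesterol synthesis genes were lower in GM15510 (9 of 16 with 0 higher, also 9 when adjusted over the list alone, median −0.26, adjusted p = 0.014), with adjusted p = 0.056 with an estimated correlation, in a range from 5.68e-11. HSD17B7 and DHCR7, enzymes of that route, each had −0.87, though another DHCR7 probe set had −0.40 and did not pass. IRF9, CKS2, PTTG1, MKI67 and HSF1 were named after their values were seen. Under median centring IRF9, CKS2 and PTTG1 had adjusted p = 0.211, 0.21 and 0.87, and HSF1 had 0.16 with the GAPDH ratio as a covariate, each the highest over its alternatives.

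Of 23 gene lists, 21 had enough members to test, which gave 35 calls in 252 tests of a list in a comparison, and 17 of the 35 held with an estimated correlation. Some lists passed in 0 comparisons by camera. DNA repair genes came lowest at 2.5 cGy in GM15510 (adjusted p = 0.28) and NF-kB target genes between the lines (adjusted p = 0.079). Apoptosis genes had adjusted p = 0.36 at 7.5 cGy in GM15036, with BID, a pro-apoptotic BCL2 relative, higher at 0.73, also 1 when adjusted over the list alone, and its other probe set had 0.045. Immediate-early genes had adjusted p = 0.12 at 5 cGy in GM15510, with 0 of 24 past limma's threshold, 2 lower when adjusted over the list alone and 6 lower at an unadjusted p under 0.05, and oxidative stress genes 0.46 at 7.5 cGy in GM15036, with FTL as the member of 25 that rose. Nucleolar genes had adjusted p = 0.26 at 5 cGy in GM15036, with 0 of 26 past limma's threshold and 1 higher and 5 lower at an unadjusted p under 0.05. B cell identity genes had adjusted p = 0.6 for the slope in GM15510, with BTK, POU2AF1 and PAX5 higher and MS4A1 lower of 21, or 4 and 1 when adjusted over the list alone. T and NK cell markers had adjusted p = 0.36 for that slope with 0 of 5 past limma's threshold and 1 higher at an unadjusted p under 0.05, and fibroblast markers 0.6 between the lines with SPARC, a matrix glycoprotein, lower at −1.68 of 5. Monocyte and erythroid markers, with 4 and 1 measured members, were too few to test.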

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

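Chosen only after the results were seen were the tests of the spike-in signal, of brightness as the whole cause of the ribosomal and of the mitosis pattern, of a shared dose response and of the GAPDH and ACTB ratios, and all settings with brightness as a covariate, without the dim arrays, with centring after scaling or with a dose left out of the slopes. The tests of other splits, of matched random lists and of predicted brightness effects were planned.

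The dimmest dose of each line had its most calls, 10 cGy in GM15036 and 2.5 cGy in GM15510. Calls rose as brightness fell in GM15036 (19, 73, 429 and 1563 at 51.3, 49.9, 32.4 and 22.1). In GM15510 they did so at 67.8, 39.0 and 18.7 (237, 558 and 1261), but the brightest dose (89.1, 10 cGy) had 787. The order of 1563, 1261 and 787 turned with brightness as a covariate (365, 114 and 900). Spike-in controls added at hybridisation followed brightness across the arrays of a line, with r = 0.98 and rho = 0.96 in GM15036 (n = 15, permutation p = 1e-05 each, the smallest the permutations can give, adjusted 2e-05 for r, and r = 0.96 without the 2 farthest arrays). In GM15510 these were r = 0.69 and rho = 0.61 (n = 15, permutation p = 0.0052 and 0.017, adjusted 0.0052 for r, and r = 0.53 without the 2 farthest arrays), so hybridisation or scanning may account for part of the brightness. The changes of GM15036 at 10 cGy correlated across probe sets, which are not independent, at 0.17 with GM15510 at 2.5 cGy and at 0.046 with GM15510 at 10 cGy, a difference of 0.12 that ranged from 0.097 to 0.17 without 1 array and does not decide whether brightness drives the calls. In GM15510 brightness did not follow dose. Every array at the dimmest doses was dimmer than at 1 cGy, so brightness and dose cannot be told apart, and a dose response stays open.

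Ribosomal protein genes rose with dose in GM15036. Their median slope of 0.0404 lay at percentile 100 of random lists matched on mean expression (−0.0146 to 0.00409 for the middle 95%), which argues against expression level as the cause. As brightness fell in GM15036 but rose in GM15510 from 1 to 10 cGy, the slopes cannot decide on a shared dose response. The GM15510 slope was down (adjusted p = 1e-06, 0.12 with an estimated correlation). The slope difference had adjusted p = 0.0029 with an estimated correlation but 0.996 under median centring. Brightness stays open, since its effect within GM15510 groups predicted 0.116 of the median change of 0.253 at 10 cGy (0.0382 to 0.146 without 1 array), and with brightness as a covariate 0.706 of the slope was left (0.435 to 0.816 without 1 array, adjusted p = 2e-12). The normalization stays open as well, although the GM15510 slope turned only under median centring, where the pseudocount was added to unscaled values. Dose, with adjusted p = 9.94e-32 for the slope without 10 cGy, remains a candidate explanation.

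Mitosis genes fell with dose in GM15036, but without 10 cGy their slope had a median of −0.0191 and adjusted p = 0.0877. Their median slope of −0.0278 over all doses lay at percentile 0.12 of matched random lists (−0.0204 to 0.00665 for the middle 95%), which argues against expression level. With the GAPDH ratio as a covariate 1.14 of the slope was left (adjusted p = 6.59e-07). The ACTB ratio left 1.29 (1.11 to 1.31 without 1 array, adjusted p = 4.8e-07) and brightness 0.799 (0.712 to 1.17, adjusted p = 1.6e-04). These fits use scatter within groups, so RNA integrity and brightness stay open. Brightness predicted −0.111 of the −0.334 at 10 cGy (−0.138 to −0.0841 without 1 array). A slower cycle at higher dose, or a culture of another density, may underlie the rest, and neither was tested here.

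Other splits of the same arrays were counted for each fit. For 3 arrays against 3, the 10 splits are too few for a share under 0.05, and only the real one gave as many calls. In GM15036 the real counts were 73, 19, 429 and 1563 at 2.5, 5, 7.5 and 10 cGy and the highest others 1, 0, 0 and 4. In GM15510 they were 1261, 558, 237 and 787, with 2, 21, 1 and 0 as the highest others. Of 100 splits, only the real one gave as many calls in each larger fit, which cultures shared within groups would give too. The shared calls test nothing here, as other splits had short lists. The real counts and highest others were 2152 and 196 for any dose difference and 1731 and 90 for the slope in GM15036, 2789 and 279 and 616 and 81 in GM15510, 2733 and 42 for the interaction, 1085 and 0 for the shared calls and 6287 and 1607 for the line difference.

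The following stood out because the slope over dose differed between the lines by the test of the difference, given as GM15510 minus GM15036 in log2 per cGy. Of 55 genes tested in this way, 25 passed. Lower in GM15510 were CYP27A1 at −0.284, POLR2J at −0.256, ICAM4 at −0.229, ATG3 at −0.218, SPN at −0.21, NUP43 at −0.208, SIGLEC6 at −0.197, ABITRAM at −0.151, EXOG at −0.15, ZNF587B at −0.109 and CDYL at −0.083. Higher were PCNA at 0.0603, SLC43A3 at 0.0739, DDB2 at 0.0828, RETREG3 at 0.0918, BAX at 0.0962, PPM1D at 0.101, MCL1 at 0.108, ATP9B at 0.114, ELF1 at 0.141, KIF3A at 0.159, HIPK2 at 0.162, PLS1 at 0.191, LRRC1 at 0.21 and SEMA5A at 0.237. With brightness as a covariate, ICAM4, NUP43, ZNF587B, SLC43A3 and MCL1 passed and the other 20 did not, and BAX turned to −0.0131 and ELF1 to −0.0439. Under median centring CDYL turned to 0.00595. Of their other tested probe sets, 1 of MCL1 passed at 0.0744, while those of ELF1 (−0.0711), LRRC1 (−0.025), SPN (0.151 and 0.0757), SIGLEC6 (0.0309) and 1 of CDYL (0.0457) had the opposite sign and did not pass, nor did the others of MCL1, CDYL, BAX, HIPK2 and ATG3. In GM15036 the other ELF1 probe set rose with dose by 0.0628 (adjusted p = 0.0274), where the named one fell. Without 10 cGy CYP27A1, SEMA5A and ATP9B passed and the other 22 did not, among which ELF1 turned to −0.069, MCL1 to −0.00657, BAX to −0.000422, RETREG3 to −0.0121 and SPN to 0.0321. Without 1 cGy DDB2, ATG3, SEMA5A, HIPK2, SLC43A3 and SIGLEC6 did not pass, without 2.5 cGy PCNA, ELF1, PLS1, ATP9B, LRRC1, SPN, SIGLEC6, EXOG and CDYL, without 5 cGy KIF3A, and without 7.5 cGy PCNA, ATG3, PLS1, ATP9B and SIGLEC6. KIF3A lost its call without 19 of the 30 arrays and PLS1 without 12 of them. Single arrays ended other calls, in GM15036 1 cGy replicate a for SIGLEC6 (0.0546), b for ATG3 (0.0545), ELF1 (0.0551), PCNA (0.0594) and SPN (0.0644), and c for ATP9B (0.0781). So did 10 cGy replicate a for PCNA (0.0522) and SLC43A3 (0.055) and b for ATP9B (0.0607), ELF1 (0.0738), SIGLEC6 (0.0653) and SPN (0.106). In GM15510 these were 1 cGy replicate 1 for ELF1 (0.0561), SIGLEC6 (0.0545) and SLC43A3 (0.0726), 2 for SIGLEC6 (0.0513) and 3 for ATP9B (0.0817), PCNA (0.0635) and SPN (0.0549). So were 10 cGy replicate 1 for ATP9B (0.0835), ELF1 (0.091), EXOG (0.0693) and PCNA (0.0831), and 3 for SIGLEC6 (0.0698), SLC43A3 (0.0623) and SPN (0.11).

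Median slope differences of 6 lists also passed, at 0.0345 for G1/S, 0.0541 for G2/M, 0.033 for cholesterol synthesis, 0.0252 for glycolysis, −0.0541 for ribosomal proteins and −0.0246 for oxidative phosphorylation. With an estimated correlation 4 of these calls were lost, with adjusted p = 0.0811 for G1/S, 0.051 for cholesterol synthesis, 0.0522 for glycolysis and 0.10 for oxidative phosphorylation. Under median centring oxidative phosphorylation turned to higher (adjusted p = 0.353) and ribosomal proteins had adjusted p = 0.996, and without the dim arrays cholesterol synthesis had 0.221, each the highest over its alternatives that kept all doses. Without 10 cGy G1/S, G2/M and glycolysis had adjusted p = 0.604, 0.141 and 0.628, without 1 cGy cholesterol synthesis had 0.311, and without 7.5 cGy cholesterol synthesis had 0.0844 and oxidative phosphorylation 0.522, with 0.413 without 2.5 cGy.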

How the results depend on the processing

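The settings chosen after seeing the data are named above. Pseudocounts of 1 and 16, robust eBayes and quantile normalization moved no count of calls by over 1.5 times, and the cause was not tested for any change below unless its setting shows it, as fewer tests or samples do. Signal over background was not measured here, and the arrays with the lowest signal were the 10 cGy replicates a and b of GM15036 and the 2.5 cGy replicates 2 and 3 and the 5 cGy replicate 1 of GM15510.

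Counts of calls that moved by over 1.5 times follow by setting, in the order of 2.5, 5, 7.5 and 10 cGy, any dose and slope where present. The threshold of 0.01 left 18, 7, 168, 837, 1216 and 979 in GM15036. GM15510 had 541, 241, 70, 410, 1527 and 276, the interaction 1647 and the slope difference 779. Median centring gave 30, 2, 4323 at 10 cGy, 3632 and 4258 in GM15036, 5688, 1961, 7, 196, 6278 and 1701 in GM15510, 5871 for the interaction, 3014 shared and 59 lists. Without a filter 2.5 cGy in GM15036 had 45, and with the 60 percent filter 5 cGy had 35. Without the trend GM15036 had 24, 5 and 232 at 2.5, 5 and 7.5 cGy, GM15510 had 71 at 7.5 cGy and 386 for the slope, and 678 were shared. Array weights gave 382 and 166 at 2.5 and 5 cGy in GM15036, and 512, 1696 and 973 at 7.5 and 10 cGy and for the slope in GM15510. Each line alone gave 30 at 5 cGy in GM15036 and 129 at 7.5 cGy in GM15510. The GAPDH ratio as a covariate gave 166, 955, 1408 and 934 at 7.5 and 10 cGy, for any dose and for the slope in GM15036. With 1 probe set per gene GM15036 had 10, 268, 961, 1338 and 1067 from 5 cGy on, GM15510 735, 316, 146, 513 and 1746 up to any dose, the line difference 3960, the interaction 1638 and the shared calls 673. Brightness as a covariate gave 134, 365, 1207 and 396 at 7.5 and 10 cGy, for any dose and for the slope in GM15036, 114, 222, 1754 and 305 at 2.5 and 5 cGy, for any dose and for the slope in GM15510, 1546 for the interaction, 505 shared and 240 of 389 named calls. Centring after scaling gave 2 and 272 at 5 and 7.5 cGy in GM15036, and 2679, 83 and 469 at 2.5, 7.5 and 10 cGy in GM15510. Without the dim arrays GM15036 had 126, 50, 677, 751 and 1055 at the 4 doses and for the slope, and GM15510 645 at 2.5 cGy. The slope without 1 cGy had 1545 calls in GM15510, and without 10 cGy 358 in GM15036 and 305 in GM15510. The slope difference had 5213 under median centring, 2196 under centring after scaling, 854 with 1 probe set per gene, 219 with brightness as a covariate and 417 without 10 cGy, against 1436. Of the named slopes called in GM15036, in GM15510 and for their difference (45, 27 and 52), 10, 2 and 14 passed in the same direction without 10 cGy, and 1, 8 and 6 turned. Of 35 list calls, 17 held with an estimated correlation, while fry, which does not compare a list with other genes, called 78.

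Leaving out each array in turn gave 16 to 88, 2 to 33, 185 to 497, 1062 to 1675, 1784 to 2294 and 1314 to 1844 calls in GM15036. In GM15510 the ranges were 732 to 1332, 285 to 604, 77 to 269, 478 to 858, 2326 to 2888 and 404 to 652. They were 6057 to 6297 for the line difference, 2357 to 2898 for the interaction, 894 to 1138 shared, 328 to 384 named calls and 28 to 37 lists, of which 23 of the 35 list calls passed each time. Where an array left a group with 2, these were assumed to vary like the other groups.

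With all doses kept, directions turned in 20 places among the lists and the genes named by rule. Under median centring RPS19, RPL12, RPL24 and RPS15 at 10 cGy in GM15036 had −0.0333, −0.0363, −0.132 and −0.108, RPS3 and DDB2 at 2.5 cGy in GM15510 −0.05 and −0.0145, the slope of CDKN1A in GM15036 −0.0096 and that of RPS18 in GM15510 0.00119. The slope differences of GINS1, RPL27, RPS19, RPS18 and CDYL turned to 0.00735, 0.015, 0.00253, 0.0141 and 0.00595. Ribosomal lists turned at 10 cGy in GM15036 (adjusted p = 0.15), at 2.5 and 5 cGy and for the slope in GM15510 (0.0217, 0.396 and 0.341), and oxidative phosphorylation for the slope difference (0.353). With brightness as a covariate the slope differences of ELF1 and BAX turned to −0.0439 and −0.0131. Of 411 named results, those that kept their direction but lost their call were 147 with brightness, 79 without the dim arrays, 76 of 410 under median centring, 57 under centring after scaling, 54 with the GAPDH ratio, 66 without the trend, 42 without a filter, 40 of 312 with each line alone, 23 under quantile normalization, 16 with array weights, 16 and 11 with pseudocounts of 1 and 16, 7 with robust eBayes, 1 with 1 probe set per gene and 0 of 323 with the 60 percent filter.

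The replicate letters and numbers of the labels did not pair the arrays. Of 30 same-numbered pairs in each line, 0 had deviations from their group means that correlated over 0.1 (highest 0.04 and 0.097), and 5 and 6 of 15 arrays correlated best with their own number. With the replicate block GM15036 had 59, 16, 407 and 1512 calls at the 4 doses and GM15510 1203, 526, 208 and 763, and the replicate block moved no count by over 1.5 times. It left 35 list calls and 369 of the 389 named calls.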

Other observations

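Of 45 DNA repair genes, 6 fell and 0 rose in GM15510 at 2.5 cGy by limma, or 7 when adjusted over the list alone, with 9 lower and 4 higher at an unadjusted p under 0.05, and the list did not pass (median −0.059, adjusted p = 0.28). PRKDC, the catalytic subunit of the kinase that joins broken DNA ends, had −0.90 (adjusted p = 2.92e-06, n = 3), FANCL, a ubiquitin ligase of crosslink repair, had −0.84 (adjusted p = 1.79e-05) and MSH6, a mismatch recognition protein, had −0.73 (adjusted p = 1.74e-05). ATR, PARP1 and MRE11, which sense damaged DNA, had −0.45, −0.46 and −0.39. These 6 were picked after their values were seen. Brightness was 18.7 at this dose against 69.4 at 1 cGy, and with brightness as a covariate 114 probe sets in all were called in this comparison.

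Of 26 NF-kB target genes, 15 were lower and 4 higher in GM15510 than in GM15036 over all doses, or 16 and 4 when adjusted over the list alone, and the list did not pass (median −0.35, adjusted p = 0.079). CCL22, a chemokine of activated B cells, had −0.76 (adjusted p = 4.23e-12), EBI3, a cytokine subunit induced by Epstein-Barr virus, −0.91 (adjusted p = 6.21e-10), and CCR7, a lymph node homing receptor, −0.58 (adjusted p = 1.17e-08), with 15 arrays per line. NFKB1, a subunit of the factor itself, was higher at 0.54 (adjusted p = 2.87e-09), and so were CD83, TNFAIP8 and CXCL8, a chemokine for neutrophils, at 0.76 (adjusted p = 0.0148). With the GAPDH ratio as a covariate TNFAIP8 and CXCL8 had adjusted p = 0.0502 and 0.149, the highest over their alternatives. These members were picked after their values were seen.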
